A study of Mus musculus with 6 samples.

How the data were processed

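RNA was extracted from pooled anterior dorsal pericardial wall and outflow tract tissue of mouse embryos at embryonic day 9.5, and libraries were made with an NEBNext Ultra kit, per the labels' protocols. The 6 samples were grouped by their genotype labels into 3 controls and 3 mutants (Hand2 floxed alleles with Mef2c-AHF-Cre), and the replicate numbers were taken from the sample titles. The number of embryos per pool is not given in the sources used here. Whether the libraries of a group came from separate litters is not stated either, so p-values measure only the spread between these libraries.

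The authors deposited 1 table of FPKM values (fragments scaled by gene length and library size) with a column per library. The submitters' processing notes list bcl2fastq 2.18, STAR 2.5.1b and Cufflinks 2.2.1 and the mouse build mm8. The annotation, the strand setting and any filters are not given in the sources used here. The table holds 25888 genes by Ensembl ID, each above 0 in at least 1 library, and 6480 of them are listed at 0 in 1 library or more. Symbols came from a reference name table, in which 129 IDs had no match. Low FPKM values were whole multiples of a step set by the gene's length and the library's depth, so whole reads were recovered. The multiple for each gene was chosen to make its values whole, so the 100% that came out whole within 0.001 is no check. The gene lengths recovered with the reads equalled the union of exons in GENCODE M21 (GRCm38) for 20310 of 25759 genes (78.8%), so the annotation was of the GRCm38 kind although mm8 is listed. For the other genes a factor common to all libraries could not be restored, so their reads may be too few by a whole factor. Coordinates are given on GRCm38. The recovered lengths of Hand2 and Hand2os1 differ from that annotation, so the exons counted by the authors are not exactly those described. The FPKM denominators differed from the plain totals of the recovered reads, which were 23190075 to 30137655. At this depth 1 read is a small part of the FPKM of the genes tested, and the number of libraries limits the precision.

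The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), two-sided, with empirical Bayes moderation and a mean-variance trend, over the 12650 genes with a mean FPKM of at least 1 over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Hand2 was also compared by an exact permutation test. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. The 36 lists were fixed before the data were examined, as were the tests, the main settings and the first set of other settings. Of their members, 917 matched a symbol exactly, 2 through a synonym and 9 not at all, and lists with at least 5 measured members were tested, 34 in all. The macrophage list (4 measured) and the sex-linked list were described by values only. In the macrophage list Cd68 had 2.95 and 3.95 FPKM in controls and mutants and Pf4 3.27 and 2.60, and no member passed in either fit (1 higher at an unadjusted p under 0.05 by limma in each).

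The genes named were Hand2, then in each direction the 12 with the largest log2 change among genes past the threshold whose groups did not overlap, leaving out names of predicted genes, clones, small RNAs and pseudogenes. Where fewer than 12 passed, the genes with the smallest p filled up and are said not to have passed. For each list described, up to 4 members with the smallest p were named. Genes named outside this rule are said to have been chosen after their values were seen. This holds for the 7 further genes past the threshold too.

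The groups share replicate numbers, and it was checked whether libraries of the same number deviate together. The correlations of their deviations from the group means over genes were 0.73, 0.44 and 0.44 for numbers 1, 2 and 3, and each library correlated best with its own number. With all 3 over 0.1 the numbers were taken to pair the libraries. Control 2 and mutant 3, of unlike numbers, also had 0.31, so this threshold does not settle the pairing of numbers 2 and 3. By the plain correlation of log2 values control 2 was closer to mutant 3 (0.992) than to mutant 2 (0.989). The blocked calls rest on this pairing. The pairing comes from the data and not from the labels, which do not say what the numbers stand for. The test was kept without the block, as fixed, and values with the replicate number as a block are given where they change a call or a count. No pair of libraries shared identical values.

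The fits were tested on simulated reads drawn for the real genes, depths and pair differences, with 200 genes changed by known folds. For the comparison of mutants with controls over 12580 simulated genes, the fit without a block recovered 8.96%, 74.6% and 95.5% of genes changed 1.5-, 2- and 4-fold, with 1 false call. With the block it recovered 88.1%, 100% and 100%, with 28 false calls, a larger share of its calls than the 0.05 aimed for, so some of the genes called with the block and not without it may be false. With voom and the block it recovered 94.0%, 97.0% and 100%, with 15 false calls. The simulated pair differences and spread were taken from the blocked fit of the real data, so the gain from the block was built in. How the block behaves if the numbers do not pair the libraries cannot be read from this simulation.

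The other settings fixed in advance were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-of-ratios rescaling, quantile normalization, rescaling to equal sums without red cell and mitochondrial genes, limma without the trend, limma with array weights, the replicate block, an adjusted p under 0.1 and each library left out. Chosen after the data were seen were limma's voom on the recovered reads with and without the block, the block after removal of each library's trend with gene length (a lowess curve with a span of 0.3), both libraries of 1 number left out, and the block with a pseudocount of 0.1, median-of-ratios rescaling or an estimated correlation. Tests on recovered reads were alternatives only, since the deposited values are FPKM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the recovery of reads and the plots.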

Results

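RNA sequencing was performed on the anterior dorsal pericardial wall and the cardiac outflow tract of mouse embryos at embryonic day 9.5. The dorsal pericardial wall behind the heart holds second heart field progenitors, the cells that are added to the growing outflow tract. Tissue was dissected from control embryos and from embryos in which floxed Hand2 was recombined by Mef2c-AHF-Cre, a Cre line active in the anterior second heart field. Hand2 encodes a basic helix-loop-helix transcription factor of the developing heart, limb and pharyngeal arches. Each group had 3 libraries, and the tissue in each was pooled from embryos whose number is not given in the sources used here. Whole reads behind the deposited FPKM values could be recovered, for some genes only up to a common factor. They summed to 25002554, 30137655 and 26564469 in control libraries 1 to 3 and to 23190075, 25844644 and 26345389 in mutant libraries 1 to 3. The comparison asks how loss of Hand2 in this Cre lineage altered the transcriptome of the region.

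Hand2 was measured first, as a check of the labels. On GRCm38 the gene (ENSMUSG00000038193) lies on chromosome 8 from 57320983 to 57324633 on the plus strand, with 2 exon blocks after merging its transcripts. Its FPKM was 116, 64.3 and 81.7 in control libraries 1 to 3 and 34.6, 22.2 and 17.9 in mutant libraries 1 to 3. The mean was 87.3 ± 26.3 (SD, n = 3) in controls and 24.9 ± 8.69 (SD, n = 3) in mutants, which is 28.6% of the control mean. All 3 mutant values lay below all 3 control values, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. The log2 fold change was -1.78 (SE 0.28), with a limma adjusted p of 0.109 without a replicate block and 0.00279 with it. Over the 24 alternative settings the adjusted p ranged from 4.79e-05 to 0.547. Which part of the gene is floxed is not given in the sources used here, so reads from a recombined allele may remain in these values. What share of the remaining reads came from such alleles or from cells without Cre activity was not measured. The antisense gene Hand2os1, on the minus strand from 57281117 to 57324233, shares 461 exonic bases with Hand2 in the reference annotation. Its FPKM was 22.8 ± 3.39 in controls and 32.8 ± 5.77 in mutants (SD, n = 3), a log2 fold change of 0.50 (SE 0.16). It did not pass without the replicate block and passed with it (limma adjusted p = 0.511 without it and 0.0106 with it, with a range of 0.00134 to 1.00 over the 24 settings). No strand setting is given for the counting, so reads from the shared bases could not be assigned to either gene.

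**Figure D1:**
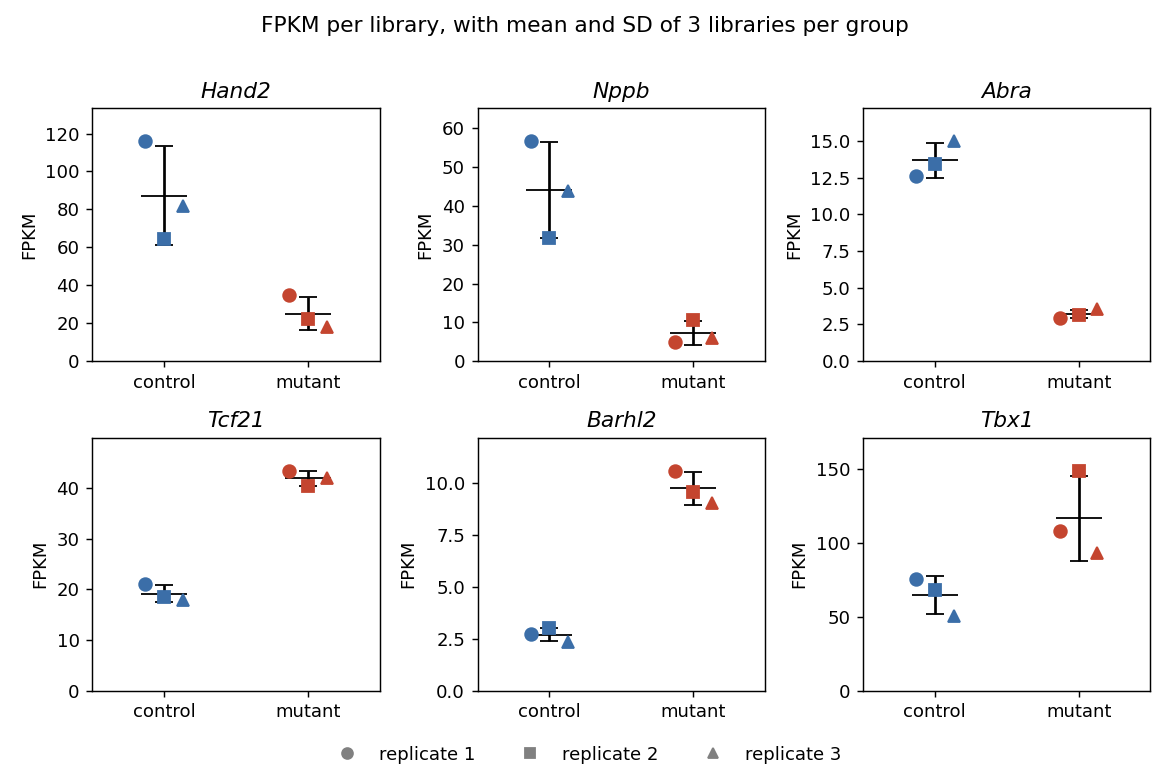
FPKM of 6 genes in each library, with control libraries in blue, mutant libraries in red and the marker shape giving the replicate number. The horizontal line is the mean and the bar the SD of 3 libraries. Hand2 averaged 87.3 in controls and 24.9 in mutants, and the groups did not overlap for any of the 6 genes.

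Of the genes that fell in the mutants, several are expressed in heart or striated muscle. Nppb, which encodes the natriuretic peptide B of heart muscle, went from 44.1 ± 12.4 FPKM in controls to 7.23 ± 3.03 in mutants (SD, n = 3 each), a log2 fold change of -2.48 (SE 0.29). Abra, a gene of striated muscle, went from 13.7 ± 1.19 to 3.22 ± 0.29, a log2 fold change of -1.80 (SE 0.10). Rgs5 and Rgs4, regulators of G protein signalling, had log2 fold changes of -1.52 and -1.08. The thin filament protein gene Lmod3 and the melusin gene Itgb1bp2, both expressed in striated muscle, had -1.13 and -1.08. Itm2a fell from 95.7 to 32.2 FPKM, Armh4 from 113 to 41.1 and Dok4 from 84.6 to 37.3. The proteoglycan gene Cspg4 fell from 6.15 to 1.88, Mtus2 from 4.84 to 1.66 and Mov10l1 from 3.64 to 1.12. The 7 further genes that fell were Gata5, Cd59a, Col8a1, Cavin2, Radil, Itga7 and Prnp, and Gata5, a cardiac zinc finger transcription factor, went from 33.1 to 15.7 FPKM.

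Only 3 genes rose at the same threshold. Barhl2, a homeobox transcription factor, went from 2.71 ± 0.33 to 9.76 ± 0.78 FPKM (SD, n = 3 each), a log2 fold change of 1.54 (SE 0.10). Tcf21, a transcription factor of the epicardium and of head muscle progenitors, went from 19.1 ± 1.68 to 41.9 ± 1.49, a log2 fold change of 1.097 (SE 0.09). Rxrg, which encodes the retinoid X receptor gamma, went from 1.19 ± 0.20 to 3.55 ± 0.37, a log2 fold change of 1.06 (SE 0.11). The next genes by p did not pass without the block and passed with it. Among these, Pitx1 had 1.41 FPKM in controls and 5.32 in mutants, the axon guidance ligand gene Slit1 2.29 and 6.37, and the GDNF receptor gene Gfra1 1.38 and 3.45. The retinol receptor gene Stra6 had 5.89 and 10.7, Lrrn1 1.85 and 4.34, and the peptide hormone gene Adm 1.86 and 3.46. Col13a1, Spaca6 and Carmil3 had log2 fold changes of 0.52, 0.44 and 0.40.

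Of 12650 genes tested with limma, 3 were higher and 19 lower in mutants at an adjusted p under 0.05. At an unadjusted p under 0.05 the counts were 329 and 546. With the replicate number as a block, 180 were higher and 468 lower, among them all 22 called without it. Array weights without the block gave 193 higher and 349 lower genes and called 414 of the 648 that the block called, so genes described as passing with the block may also have passed there. Of the blocked calls, 7 higher and 35 lower genes changed at least 2-fold on the log2(FPKM + 1) scale. Rescaling to equal sums without red cell and mitochondrial genes gave 4 higher and 9 lower genes, and voom on the recovered reads gave 478 higher and 761 lower with the block. The groups did not overlap for 12.3% of the genes tested, against 10% by chance if the 6 libraries were exchangeable. Libraries of the same number deviated together, so 10% is not a fair reference here. By limma without the block, the real grouping gave 875 genes at an unadjusted p under 0.05. The other splits that part all 3 pairs gave 67, 83 and 53. Of the 648 blocked calls the groups did not overlap for 431, so in the rest control and mutant values overlapped. Without mutant replicate 2 the unblocked fit called no gene (176 higher and 311 lower at an unadjusted p under 0.05), and without any other single library it called 1 to 3 genes. Abra passed in 5 of these 6 fits, Barhl2 in 3 and Tcf21 in 1, and none of the other 19 genes passed in any fit that tested it. Col8a1 (1.65 FPKM in controls and 0.37 in mutants) was tested in 3 of the 6, since without any 1 control library it fell under the filter.

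The libraries differed in ways that the groups did not explain. The first principal component, with 46.9% of the variance, set the libraries numbered 1 in both groups apart from the other 4. In those libraries, cytosolic ribosomal protein genes took 6.59% and 6.33% of the reads, against 4.22% to 4.76% in the others. The second component, with 29.4% of the variance, did part the groups. Mutant libraries 1 to 3 lay at 8.39, 17.1 and 6.49 on it, and control libraries 1 to 3 at -8.77, 1.04 and -24.2. The library of control replicate 3 held transcripts of yolk sac and liver endoderm that were near 0 elsewhere. Afp was at 127 FPKM there and at most 0.64 in the other 5 libraries, Apoa1 at 189 against at most 1.60, and Ttr at 123.1 against at most 1.0502. Of the 18 genes on the list of yolk sac and liver genes that are in the table, 17 were highest in that library, where the list made up 0.230% of the FPKM sum. In the other libraries it made up at most 0.00313%. Its 13 measured members, of which 9 reached a mean FPKM of 1 only through that library, were lower in mutants (median log2 fold change -1.28, camera adjusted p = 0.00124, adjusted p = 0.666 with an estimated correlation). None passed in either limma fit on FPKM, and none had an unadjusted p under 0.05 there. By voom on the recovered reads with the block, 12 of them were called lower. Without control replicate 3 only 4 members were measured, fewer than the 5 required of a list test, and their median was -0.09. Xist was at 10.8 to 36.3 FPKM and the Y-linked Ddx3y at 1.61 to 3.33 in the 6 libraries, so each pool held both sexes.

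**Figure D2:**
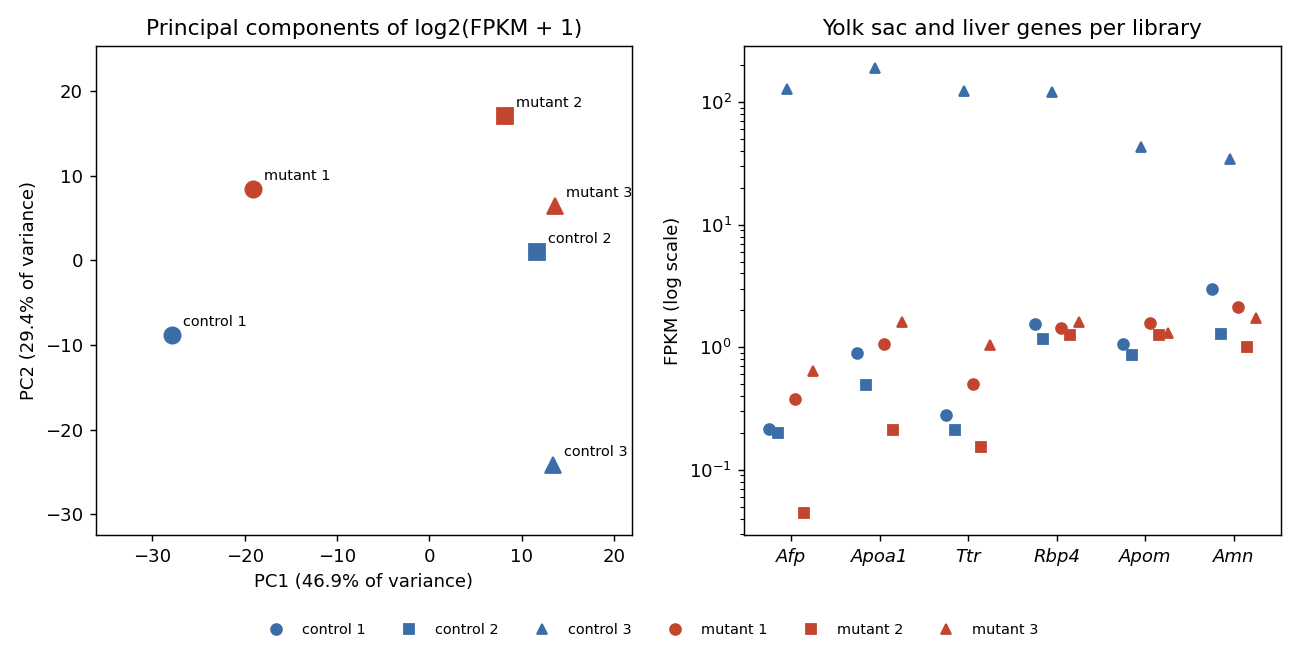
Left, the first and second principal components of log2(FPKM + 1) for the 6 libraries, with 46.9% and 29.4% of the variance. Right, FPKM on a log scale of 6 yolk sac and liver genes in each library. Both libraries numbered 1 lie apart on the first component, and all mutant libraries lie above all control libraries on the second. Control replicate 3 has Afp at 127 FPKM against at most 0.64 in the others.

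The cardiac muscle list had the lowest median after that one. Of its 33 measured members, 1 fell without the block (Nppb) and 26 with it, none rose, and 7 passed in neither fit. The counts adjusted over the list alone were 17 lower without the block and 28 with it. The median log2 fold change was -0.68 (camera adjusted p = 1.03e-19, adjusted p = 0.263 with an estimated correlation). Nppa had 3.00 ± 1.01 FPKM in controls and 0.28 ± 0.28 in mutants, the pacemaker channel gene Hcn4 12.1 ± 2.21 and 5.75 ± 0.83, and Smpx 10.2 ± 1.78 and 4.51 ± 1.35 (SD, n = 3 each). These 3 did not pass in the test without the block and passed with it. The members did not all move alike. Actc1, the cardiac alpha-actin gene, had 2649 FPKM in controls and 1456 in mutants and passed with the block. The myosin genes Myh6 (228 and 214) and Myl2 (202 and 204) passed in neither fit, and these 3 genes were chosen after their values were seen. The log2 fold change of Myl2 was -0.03 and turned positive under quantile normalization and under rescaling to equal sums. With the block, 27, 21 and 18 members fell when both libraries numbered 1, 2 or 3 were left out.

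**Figure D3:**
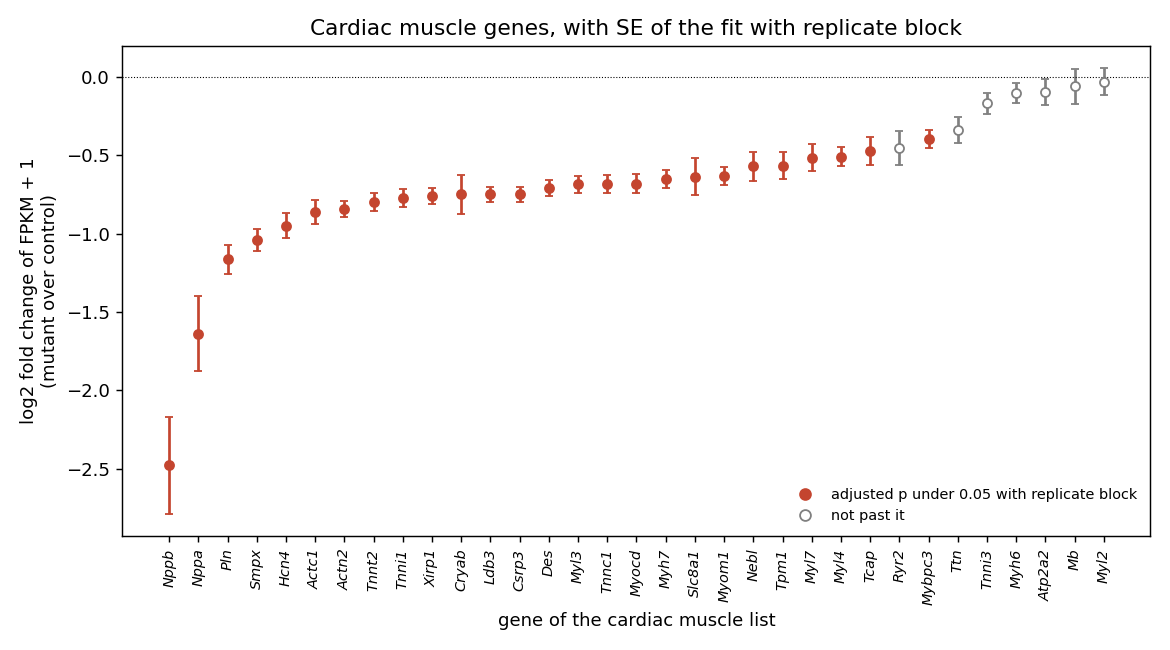
Log2 fold change of FPKM + 1, mutant over control, for the 33 measured genes of the cardiac muscle list, with the SE of the limma fit with the replicate block. Filled points are the 26 genes past an adjusted p of 0.05 in that fit. Nppb lies at -2.48 and Myl2 at -0.03.

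Smooth muscle contractile genes were also lower. Of 15 measured members none passed without the block (7 lower at an unadjusted p under 0.05) and 9 fell with it. When adjusted over the list alone, 6 fell without the block, and 12 fell and 1 rose with it. The median was -0.55 (camera adjusted p = 8.03e-08, adjusted p = 0.274 with an estimated correlation). The actin gene Actg2 had 2.40 FPKM in controls and 0.94 in mutants, Lmod1 9.27 and 5.67, Synpo2 12.2 and 7.36, and the calponin gene Cnn1 85.0 and 49.5. All 4 passed with the block and not in the test without it, as did Acta2 (1446 and 830), which was chosen after its values were seen. Of these, Actg2, Cnn1 and Acta2 also passed with array weights and no block. Without the libraries numbered 2 or 3, 5 and 4 members fell with the block.

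Endothelial and endocardial genes shifted less. None of 30 measured members passed without the block (13 lower at an unadjusted p under 0.05), and 10 fell with it. The counts adjusted over the list alone were 1 and 23. The median was -0.25 (camera adjusted p = 1.13e-10, adjusted p = 0.263 with an estimated correlation). The VE-cadherin gene Cdh5 had 40.4 ± 0.93 FPKM in controls and 29.3 ± 1.72 in mutants (SD, n = 3 each). The TGF-beta coreceptor gene Eng had 28.8 and 19.1, Emcn 5.21 and 3.54, and Pecam1 8.85 and 6.61, and all 4 passed with the block and not in the test without it. Cdh5, Eng and Emcn were among those that also passed with array weights and no block. Without the libraries numbered 1, 2 or 3, 3, 5 and 4 members fell with the block. Red cell genes, which mark blood in the pools, were lower too (26 measured, median -0.15, camera adjusted p = 0.0175, adjusted p = 0.761 with an estimated correlation), with no member past either limma fit (1 lower at an unadjusted p under 0.05 without the block and 4 with it). The red cell list was called in 17 of 24 alternative settings and lost its call without control replicate 1, control replicate 3 or mutant replicate 2, among others (adjusted p up to 0.537).

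Nuclear genes of oxidative phosphorylation had a median of -0.20 over 40 measured members (camera adjusted p = 0.00019, adjusted p = 0.719 with an estimated correlation). This list was called in 22 of 24 alternative settings and lost its call without control replicate 1 or mutant replicate 2 (camera adjusted p up to 0.687). The limma counts of its members follow. None passed without the block (1 lower at an unadjusted p under 0.05) and 8 fell with it. The counts adjusted over the list alone were 0 without the block and 25 lower with it. The complex III gene Uqcrc2 had 54.0 and 44.3 FPKM and cytochrome c (Cycs) 59.8 and 45.8, both past the blocked fit, while Ndufs1 (11.4 and 9.81) and Sdhc (35.6 and 29.6) passed in neither. Without the libraries numbered 1, 2 or 3, 0, 2 and 0 members fell with the block. In the libraries numbered 1 the list lay higher than in the rest of their group, by medians of 0.59 in controls and 0.50 in mutants on the log2 scale. Immediate-early and dissection stress genes had a median of -0.20 over 19 members (camera adjusted p = 0.000705, adjusted p = 0.363 with an estimated correlation). None passed without the block (6 lower at an unadjusted p under 0.05) and 4 fell with it, among them Fos (1.79 and 0.88 FPKM), Klf4 (5.45 and 3.69) and Dusp1 (13.7 and 11.1). The counts adjusted over the list alone were 1 lower without the block and 9 with it, and Btg2 (7.45 and 5.83) passed in neither fit over all genes. When both libraries of any 1 number were left out, 1 member fell with the block.

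Second heart field genes split. Of 22 measured members none passed without the block (5 higher and 3 lower at an unadjusted p under 0.05), and with it 6 rose and 1 fell. Tbx1, a T-box factor of the pharynx and the second heart field, had 65.1 ± 12.9 FPKM in controls and 117 ± 28.8 in mutants (SD, n = 3 each). Six2 had 8.97 ± 0.35 and 16.1 ± 5.48, Eya1 4.04 ± 1.04 and 6.16 ± 0.25, and the semaphorin gene Sema3c 9.93 ± 1.85 and 16.4 ± 3.90. These 4 rose with the block and did not pass in the test without it. Of the members chosen after their values were seen, Tbx2 (51.9 and 85.8) rose and the progenitor marker Isl1 (19.95 and 15.83) fell with the block and did not pass in the test without it. Adjusted over the list alone, none passed without the block, and 9 rose and 4 fell with it. The list as a whole passed with the block and not in the test without it (median 0.08, camera adjusted p = 0.06 without it and 0.0341 with it, adjusted p = 0.576 with the block and an estimated correlation, with a range of 0.00291 to 0.14 over the 24 settings). Without the libraries numbered 1, 2 or 3, 4 members rose with the block each time, and 0, 1 and 0 fell. The list lost its blocked call without both libraries numbered 2 (camera adjusted p = 0.115) and with the length trend removed (0.0582). It was called in 11 of the 24 settings.

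Several signalling lists were higher in mutants by small medians. Lists of other kinds had medians of like size, 0.17 for anterior Hox genes, 0.17 for surface ectoderm and 0.15 for somite and skeletal muscle. The BMP and Notch signalling lists, called in neither fit, had medians of -0.06 and 0.01. The cause of these shifts was not tested. The retinoic acid list (15 measured, median 0.17, camera adjusted p = 0.00816, adjusted p = 0.352 with an estimated correlation) had no member past the unblocked fit (2 higher at an unadjusted p under 0.05) and 3 that rose with the block, Stra6, Rarg (10.6 and 13.3 FPKM) and 1 other. Adjusted over the list alone, 1 rose without the block, and 4 rose and 1 fell with it. The retinol dehydrogenase gene Rdh10 (5.98 and 7.73) and the retinoic acid hydroxylase gene Cyp26b1 (7.13 and 5.48) passed in neither. The FGF list (20 measured, median 0.17, camera adjusted p = 0.000705, adjusted p = 0.581 with an estimated correlation) had none past the unblocked fit (2 higher and 1 lower at an unadjusted p under 0.05) and 2 that rose with the block, among them the receptor gene Fgfr1 (24.1 and 29.6). Adjusted over the list alone, none passed without the block, and 10 rose and 1 fell with it. Fgfr3 (4.11 and 2.67), Fgfr2 (5.09 and 6.19) and the ligand gene Fgf8 (29.1 and 37.6) passed in neither. Leaving out both libraries numbered 1, 2 or 3 left 1, 1 and 0 blocked calls in the FGF list and 3, 1 and 1 in the retinoic acid list. Without both libraries numbered 2 the retinoic acid list had a median of 0.02 and lost its blocked call (camera adjusted p = 0.0873). The hedgehog list (15 measured, median 0.18, camera adjusted p = 0.00121, adjusted p = 0.263 with an estimated correlation) had no member past either limma fit over all genes (3 higher at an unadjusted p under 0.05 without the block and 5 with it). Over the list alone, none passed without the block and 5 rose with it.

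The Wnt list (31 measured, median 0.17, camera adjusted p = 0.000629, adjusted p = 0.263 with an estimated correlation) held members that moved both ways. None passed without the block (7 higher and 2 lower at an unadjusted p under 0.05), and 3 rose and 3 fell with it. The ligand gene Wnt2 fell from 12.8 ± 1.68 to 6.80 ± 0.42 FPKM (SD, n = 3 each) with the block, while the Wnt antagonist gene Frzb (6.59 and 9.26) and the Wnt target Axin2 (5.93 and 7.68) rose. Rspo2 (1.04 and 1.63) passed in neither. Leaving out both libraries numbered 1, 2 or 3 gave 3, 1 and 0 blocked calls higher and 1, 2 and 1 lower. Adjusted over the list alone, 2 rose and 1 fell without the block, and 10 rose and 4 fell with it. The semaphorin and axon guidance list was similar (32 measured, median 0.17, camera adjusted p = 7.44e-05, adjusted p = 0.537 with an estimated correlation). None of its members passed without the block (9 higher and 3 lower at an unadjusted p under 0.05), and 5 rose and 4 fell with it. The receptor gene Nrp2 fell from 21.8 ± 4.50 to 9.43 ± 1.88 FPKM and Slit3 from 18.0 to 14.2 with the block, and Slit1 and Sema3f (21.2 and 27.7) rose with it. The blocked calls were 3 higher and 1 lower, 2 and 1, and 2 and 2 when both libraries numbered 1, 2 or 3 were left out. Over the list alone, 2 rose and 1 fell without the block, and 14 rose and 4 fell with it.

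The neural crest list (21 measured, median 0.10, camera adjusted p = 0.0233, adjusted p = 0.581 with an estimated correlation) had none past the unblocked fit (5 higher and 1 lower at an unadjusted p under 0.05). The list was called in 18 of 24 alternative settings and lost its call under quantile normalization, at a mean FPKM of at least 5 and without some libraries (adjusted p up to 0.154). With the block 5 rose and 1 fell, and adjusted over the list alone none passed without the block, and 8 rose and 1 fell with it. The nerve growth factor receptor gene Ngfr (5.80 and 8.61 FPKM) rose and Nrp1 (15.3 and 12.1) fell with the block, and Alx4 (1.91 and 2.83) and Tfap2b (0.82 and 1.37) passed in neither. When both libraries numbered 1, 2 or 3 were left out, 5, 1 and 3 members rose and none fell with the block. The somite and skeletal muscle list (5 measured, median 0.15, camera adjusted p = 0.0142, adjusted p = 0.281 with an estimated correlation) had Tcf21 as its 1 called member in both fits. Tcf21 was also the 1 called member of the epicardial list, whose median over 10 measured members was -0.14 while its test pointed up without the block and down with it (camera adjusted p = 0.851 and 0.957).

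**Figure D4:**
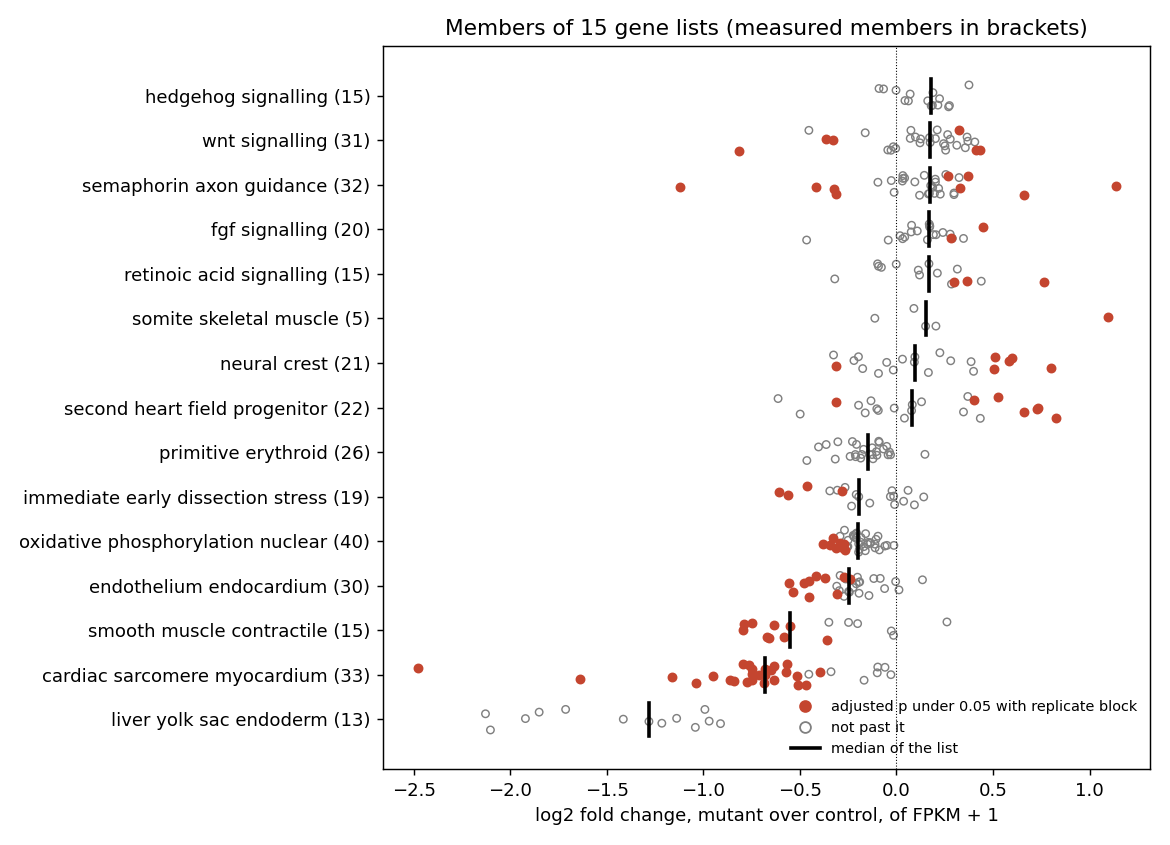
Log2 fold change of FPKM + 1, mutant over control, for each measured member of 15 gene lists, with the black line at the list's median. Filled points passed an adjusted p of 0.05 in the limma fit with the replicate block. The cardiac list has its median at -0.68 with 26 filled points, and the yolk sac and liver list at -1.28 with none.

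Of 34 lists tested, 14 were called without the block, 7 in each direction, and 17 with it. No list was called with an estimated correlation (6 of 34 at an unadjusted p under 0.05) or by fry's directional test without the block (6 of 34). The directional test with the block called the cardiac list alone (fry adjusted p = 0.0268). Fry's mixed test, which asks for change in either direction, called some lists without the block. Its adjusted p was 0.000671 for Wnt, 0.00231 for semaphorin and 0.0419 for second heart field genes. For the FGF and neural crest lists, not called by it, it was 0.356 and 0.229. Besides the second heart field list, the anterior Hox list (camera adjusted p = 0.0549 without the block and 0.0363 with it) and the neural tube list (0.0872 and 0.0196) were called with the block and not in the test without it. With the block and an estimated correlation their adjusted p was 0.616 and 0.570. They were called in 14 and 12 of the 24 settings, and without both libraries numbered 2 both lost the blocked call (adjusted p = 0.333 each), with medians of 0.06 and 0.0067 against 0.17 and 0.36. The other 17 lists were called in neither fit. Cell cycle genes had a median of 0.02 over 35 measured members and p53 and apoptosis targets 0.01 over 27 (camera adjusted p = 0.474 and 0.851). No member of either passed in either limma fit. At an unadjusted p under 0.05, no cell cycle gene was past the unblocked fit and 1 was higher with the block, while 1 p53 target was lower without the block, and 1 was higher and 4 lower with it. Extracellular matrix genes (38 measured, median -0.04, camera adjusted p = 0.836) and endocardial cushion genes (24 measured, median -0.02, camera adjusted p = 0.764) had blocked calls in both directions, 2 higher and 2 lower in the first and 2 higher and 5 lower in the second.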

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

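The voom fits, the removal of the length trend, the fits without both libraries of 1 number and the block combined with another setting were chosen after the data were seen. The counts of called genes, 3 higher and 19 lower without the block, depended most on the replicate block and on array weights. The block gave 180 and 468 called genes, 180 and 478 with a pseudocount of 0.1, 204 and 440 with median-of-ratios rescaling, 224 and 462 with the length trend removed, and 478 and 761 with voom. With the block and without both libraries numbered 1, 2 or 3 the counts were 94 and 246, 54 and 229, and 80 and 210, with fewer libraries. All 22 genes called without the block were called again in each of the blocked fits on 6 libraries, and 21 or 22 of them in those on 4. Array weights gave 193 and 349. Without the filter 5 were higher and 3 lower among 25888 genes, at a mean FPKM of at least 5 there were 11 lower, with equal sums 9 lower, and at an adjusted p under 0.1 there were 35 lower. Without both libraries numbered 1 and without the block 1 was higher and 2 lower. Leaving out 1 library gave 0 to 2 higher and 0 to 2 lower genes by limma. The lowest of these counts was without mutant replicate 2, with 176 higher and 311 lower at an unadjusted p under 0.05. No gene was higher without control replicate 3 (194 higher at an unadjusted p under 0.05) or mutant replicate 3 (317). Why these fits differ was not tested.

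Hand2 was lower in all 24 alternatives. It passed the threshold with the replicate block (log2 fold change -1.78, adjusted p = 0.00279), with the block and a pseudocount of 0.1 (-1.82, 0.0027), with the block and median-of-ratios rescaling (-1.77, 0.00306), with the block and the length trend removed (-1.74, 0.00397), and with voom and the block (-1.81, 4.79e-05). It also passed with array weights (-1.76, 0.00401), with equal sums (-1.72, 0.0443), and with the block without both libraries numbered 1 (-1.81, 0.00545), 2 (-1.92, 0.0165) or 3 (-1.60, 0.00295). Its range over the fits without 1 library was -2.03 to -1.55, past the threshold in none.

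The 14 called gene lists fell to 0 with an estimated correlation in camera (6 at an unadjusted p under 0.05) and to 0 by fry's directional test (6). They fell to 0 with the block and an estimated correlation (3), and ranged from 8 to 19 without 1 library, with 8 without mutant replicate 2. The cardiac, smooth muscle, endothelial, hedgehog and Wnt lists were called in all 24 alternatives that kept the preset correlation. The yolk sac and liver list had a median of -2.0 without control replicate 2. Without control replicate 3 its median stayed negative, at -0.0912 over the 4 members still measured, while the direction of its camera test turned. Fewer members were left than a list test requires, so this direction is not read. Tests on those 4 members are still counted among the alternatives. Among 336 values of the 14 called lists under the alternatives, 310 kept direction and side of the threshold, 25 lost the call and this 1 turned. The red cell list was called in 17 of 24 alternatives, the neural crest list in 18 and the somite list in 21. The FGF, retinoic acid, oxidative phosphorylation and yolk sac lists were called in 22, and the immediate-early and semaphorin lists in 23. Most of these calls were lost without control replicate 1, control replicate 3 or mutant replicate 2. The replicate block changed no call of a list called without it.

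For the 97 other genes named, 2295 values were computed under the alternatives, of which 1603 kept direction and side, 501 passed where they had not in the unblocked fit, 182 no longer passed and 9 changed sign. The 9 belong to Myl2 and Myh6, which passed in no fit. Myl2 had 0.0442 with quantile normalization, 0.0323 with equal sums, 0.17, 0.02 and 0.28 without control replicate 1, control replicate 3 or mutant replicate 2, 0.0118 with the block and the length trend removed, and 0.032 and 0.0253 with the block and without both libraries numbered 2 or 3. Myh6 had 0.0585 without mutant replicate 2. Over the fits without 1 library the lowest values were -0.345 for Myl2 without mutant replicate 1 and -0.203 for Myh6 without mutant replicate 3, and over all alternatives they were -0.415 and -0.361, with array weights. The cause was not tested. Of these genes, 62 passed with the replicate block that did not pass without it, and none lost a call with it.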

Other observations

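The genes in this paragraph and the next were chosen after their values were seen, and unless said otherwise each passed with the replicate block and not in the limma test without it. Some of them also passed without the block in other settings, such as Acta1 and Cdkn1c under quantile normalization and equal sums. Several further muscle genes were lower in all 3 mutant libraries. Acta1, the skeletal alpha-actin gene also expressed in embryonic heart, had 306 ± 76.1 FPKM in controls and 119 ± 1.95 in mutants (SD, n = 3 each). The small heat shock gene Hspb7 had 72.4 and 31.8, the ubiquitin ligase genes Asb2 and Trim55 60.7 and 28.3, and 48.6 and 23.3, and the calsequestrin gene Casq1 57.3 and 28.4. The methyltransferase gene Smyd1 had 85.8 and 47.1, the Popeye domain genes Popdc2 and Bves 85.8 and 46.9, and 23.02 and 12.31, and the trabecular growth factor gene Bmp10 1.84 and 0.37. Of the caveolar coat genes, Cavin1 had 50.7 and 25.0, and Cavin2, which also passed without the block, 6.08 and 2.69. The Nodal coreceptor gene Tdgf1 had 21.8 ± 2.24 and 5.80 ± 2.25, and the cell cycle inhibitor gene Cdkn1c 156 ± 33.8 and 71.2 ± 13.2.

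Among the genes higher with the block, 6 transcription factor genes were picked. Whether such genes rose more often than others was not tested. Foxl2 had 16.7 ± 4.16 FPKM in controls and 30.7 ± 10.7 in mutants, Foxd2 9.64 ± 4.47 and 17.1 ± 6.33, Foxe3 4.65 ± 2.54 and 8.48 ± 4.78, Barx1 12.9 ± 8.60 and 22.4 ± 11.7, Nr2f1 11.1 ± 3.85 and 17.95 ± 4.05, and Dlx5 12.5 ± 3.39 and 17.9 ± 1.71 (SD, n = 3 each). Their spread within a group was wide, and the groups overlapped for Foxd2, Foxe3, Barx1 and Nr2f1. Without the block the limma adjusted p of these 6 genes was 0.540 to 0.901.

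Of the tests that follow, the 1 on the fixed yolk sac and liver list and the 1 on the neural crest list were chosen after the results they measure were seen. The lower level of cardiac muscle genes in mutants was set against 2 explanations, 1 in the makeup of the tissue and 1 technical. If mutant pools held a smaller share of cardiac muscle of unchanged kind, the members would fall by about the same factor, but with the replicate block 9 of the 33 changed relative to the list mean of their own library, Nppb, Pln and Smpx below it and Myh6 and Myl2 among those above it, as was Mb, which at a mean FPKM of 1.149 may owe this to the pseudocount. Without the block only Nppb did so (adjusted p over the list = 0.0266). A trend with gene length is also argued against, since 96.15% of the members called with the block stayed called (96.2%, 25 of 26) after it was removed. A smaller share of some kinds of cardiac muscle, such as that of the outflow tract against other myocardium in the dissection, and lower transcription in the same cells both stay open, and the design does not separate them.

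The yolk sac and liver genes in the library of control replicate 3 may come from yolk sac tissue in that pool. All measured members of the fixed list (100%, 13 of 13) were highest there, but this cannot tell, since 9 of them were measured only through that library. Of a second list of such genes, written after the pattern was seen but before these values were looked at, 88.89% of the detected members were highest there (88.9%, 16 of 18, against 16.7% by chance). In that library 22 genes lay over 10 times above every other library, and in any other library at most 1 did. Since these genes stand out in 1 control library, no biological explanation that follows the groups was tested. Red cell transcripts brought with such tissue stay open as a part of the lower median of the red cell list. That list took 0.494% of the reads in control replicate 3, 0.631% in control 1, 0.321% in control 2 and 0.342% to 0.447% in mutants. With the block its median was -0.12 without both libraries numbered 3 and -0.08 without both numbered 1, against -0.15 with all.

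Barhl2, Tcf21 and Rxrg, with log2 fold changes of 1.54, 1.097 and 1.06, were set against 3 changes in tissue makeup. More neural tissue was taken to raise the neural tube list about as much as Barhl2. Its median over 5 measured members was lower, at 0.36 (0.3598, SD 0.25). Only these 5 of the 22 fixed members were measured, all 5 were higher in mutants, and 2 passed with the block. The list passed with the block (camera adjusted p = 0.0196, and 0.570 with an estimated correlation), and its median was 0.0067 without both libraries numbered 2. Members also expressed in other tissue would rise less than Barhl2, so this cannot tell and more neural tissue stays open. More epicardial or mesothelial tissue would raise the epicardial list as it does Tcf21, but without Tcf21 its median was -0.15 (SD 0.21). A relative gain from less cardiac muscle would raise other cell types alike, and the neural crest list had a median of 0.10 (0.09574, SD 0.33). A small neural or mesodermal cell population marked by these genes and higher transcription within the same cells stay open as hypotheses, and neither was tested.

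The real grouping gave 22 called genes without the block, and the highest of the other splits of the 6 libraries gave 0 (limma, up to 2908 genes at an unadjusted p under 0.05). Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The split with 2908 genes put both libraries numbered 1 together, which points to a structure of the samples by number. With the block, the real grouping gave 648 genes, and the highest of the other splits that part all 3 pairs gave 0 (up to 322 at an unadjusted p under 0.05). Here 1 of 4 splits gave as many, and 4 are too few for a share under 0.05.

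The position of the libraries numbered 1 was also measured against gene length and red cell genes after it had been seen, and these values are given without weighing. Their difference from the rest of their group correlated with gene length across genes with a Spearman correlation of -0.51 in both groups, where genes are not independent replicates. The medians of the red cell list were 0.31 and 0.06 above the rest of the group in controls and mutants.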
